A study of Caulobacter vibrioides with 6 samples.

How the data were processed

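RNA sequencing libraries of 6 samples were used, 2 each of wild type at 5 mM K+, wild type at 0.025 mM K+ and DkdpE at 0.025 mM K+. Per the labels' protocols, the cells grew at 30°C in M2G-K medium to mid-exponential phase, and libraries were made from total RNA after depletion of ribosomal RNA. Per the file headers, reads were assigned to genes with featureCounts. DESeq2 is named per the submitters' processing notes, without a version. The aligner, the genome build and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be told apart, and no coordinates are given.

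The authors deposited 2 tables of normalised counts, a signal that is each gene's read count divided by 1 size factor per library, scaled within the 4 libraries of each table. They also deposited 2 comparison tables. The mean signal (base mean) in them is, per the file headers and the values, the mean of the 4 normalised counts. The log2 fold change, the ratio (fold change) and the p-value with its adjusted p-value are the authors' own, from their comparison of the same libraries, per the file headers. Values from these tables appear only where the authors' deposited table is named.

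All 4097 gene identifiers matched the reference table of assembly ASM2200v1, used for names, gene types and the order of neighbours. A symbol was found for 777 genes, 671 from that table and 106 from product names; the others are named by identifier. Every value in the tables of normalised counts was a whole multiple of 1 step per column within 1e-06, which gave back whole reads. These reads served for the depth of each library, from 33456682 to 97757773, for the identity of columns between the tables, and for the fit of all 6 libraries, scaled by median-of-ratios factors. No count model was run on them, since 32 to 83 low values per column were fewer than the 100 needed to establish the steps independently. The reads of pair A were equal in both tables in all 4097 genes, under headings that name different potassium levels. No column was left out.

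Each comparison was fitted in its own table with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean, on log2(normalised count + 1), for genes with a mean normalised count of at least 10. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Called genes are those past it. DkdpE was set against pair B in a fit of all 6 libraries, which shared 1 estimate of the spread. Gene lists with at least 5 tested members were compared with the other genes by camera at a preset correlation of 0.01, adjusted over the 21 lists tested, then with an estimated correlation, and by fry. Of 25 lists, the 3 with fewer members (other potassium transport, sodium and proton antiport, and compatible solutes and osmotic genes) are given gene by gene, and ribosomal RNA is given as a share of reads from 2.85% to 4.89%. The lists were the Kdp operon, nitrogen and glutamate, ribosomal proteins, ATP synthase and respiration, central carbon metabolism, flagellum and chemotaxis, pilus and holdfast, swarmer and stalked cell markers, cell cycle, TonB-dependent transport, heat shock and proteolysis, general stress, envelope stress, phosphate uptake, iron, FixLJ, the SOS response, aminoacyl-tRNA synthetases, amino acid biosynthesis, and the S-layer with surface polysaccharides. The comparisons, tests, lists, rule for named genes and most alternatives were fixed before the data were examined.

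Named genes were, for each main comparison, every Kdp gene; the 10 largest increases and 10 largest decreases among called genes with a mean of at least 50 and no overlap between groups; up to 3 called members of each list with the largest change, or the 1 with the smallest p where none was called; and the 8 genes called in both comparisons with the largest product of changes, in opposite and in the same direction. For the genes called in both comparisons, 100 simulations of unchanged groups that shared libraries gave the value by chance. The fit was tested on simulated data with 200 changed genes: for the wild-type pairs (4002 genes), 35.8%, 95.5% and 100% of changes of a log2 of 0.5, 1 and 2 were called, and 4.35% of the calls were unchanged genes. For DkdpE against pair A (4007 genes) the shares were 37.3%, 95.5% and 100%, and 8.28% of the calls were unchanged genes. The simulated spread was drawn independently for each gene. Deviations that many genes of a library share were not simulated, so these shares may not hold for the real data.

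Alternatives were pseudocounts of 0.5 and 8, no filter and a minimum mean of 50, scaling to equal totals, by a trimmed mean of ratios and by quantiles, limma without the trend and with robust variances, a replicate block, an adjusted p threshold of 0.01, a minimum log2 change of 1, and each library left out in turn. Where 1 library was left in a group, its spread was taken to be that of the other group. A call lost or gained in such a fit can come from that spread as well as from the library left out. Figures and tables used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.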

Results

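RNA of Caulobacter crescentus NA1000, a freshwater bacterium, was sequenced after depletion of ribosomal RNA from mid-exponential cultures in minimal medium whose K+ was set to 0.025 mM or 5 mM. The labels gave 3 groups of 2 samples each: wild type at 5 mM K+, wild type at 0.025 mM K+, and a mutant without kdpE (DkdpE) at 0.025 mM K+. KdpE is the response regulator that works with the sensor kinase KdpD and controls the Kdp ATPase, a high-affinity potassium uptake pump. The tables did not give 1 wild-type pair the same potassium level throughout. The pair headed high K+ in the potassium table of normalised counts held the same reads, in all 4097 genes, as the pair headed low K+ in the deletion table. That pair is called pair A, and the other wild-type pair, present in the potassium table alone, pair B, so that 8 columns held 6 distinct libraries. Fold changes between them are given as pair A over pair B, which means low over high potassium by 3 of the 4 tables, and high over low by the header of the potassium table of normalised counts. Total reads in genes were 34263896 and 33456682 in pair A, 33857917 and 35145953 in pair B, and 97757773 and 34093430 in DkdpE. Ribosomal RNA took between 2.85% and 4.89% of these reads.

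The deleted gene was looked at first. In the DkdpE libraries, kdpE had 31 and 19 reads, or 13.9 and 25.7 normalised counts, against 3984 and 4025 in pair A of the same table. In the potassium table, which was scaled on its own, kdpE had 3057 and 3119 normalised counts in pair A and 514 and 503 in pair B. The kdpE reads thus went with the genotype labels of all 6 libraries; they say nothing by themselves of the potassium labels. Errors beside log2 fold changes are standard errors from limma, with n = 2 libraries per group throughout. The labels do not say that replicates were separate cultures, so the adjusted p-values measure only the spread between these samples.

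The wild-type pairs were compared to ask which genes respond to potassium. The Kdp genes held the 3 largest increases in pair A over pair B among the named genes. The B chain of the ATPase (CCNA_01664) was 161-fold higher (log2 fold change 7.33 ± 0.25, adjusted p = 8.19e-05), with 78442 and 137466 normalised counts in pair A against 637 and 648 in pair B. The A chain (CCNA_01663) was 137-fold higher (7.10 ± 0.34) and the C chain (CCNA_01665) 58.0-fold higher (5.86 ± 0.19). The kinase gene kdpD was 26.4-fold higher (4.72 ± 0.15) and kdpE 6.06-fold higher (2.60 ± 0.11). All 5 Kdp genes passed the test over all genes, adjusted over the list alone, and under every alternative that was run. As a list they rose by camera (adjusted p = 2.64e-05; adjusted p = 0.690 with an estimated correlation).

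**Figure D1:**
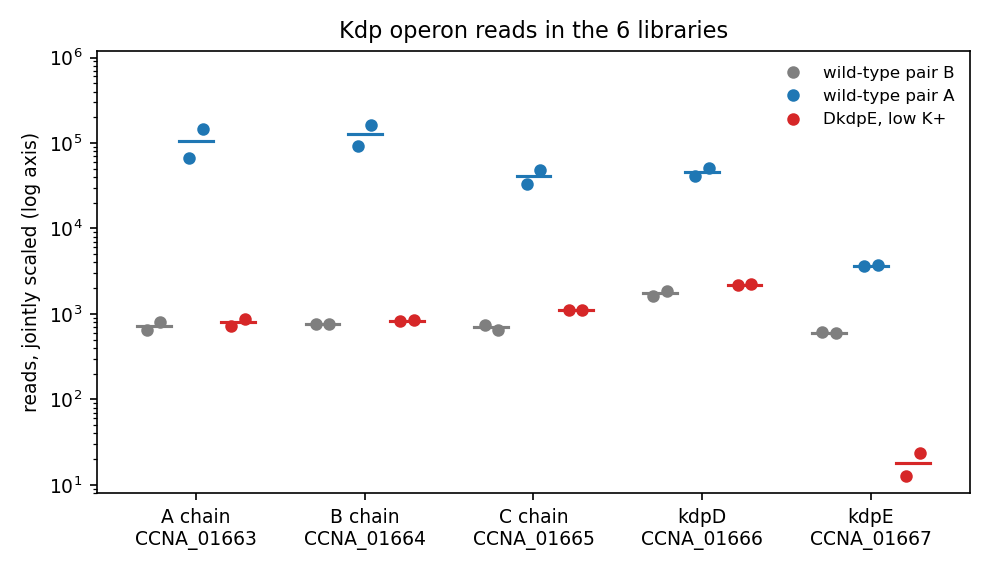
Reads of the 5 Kdp genes in each of the 6 libraries, scaled jointly (vertical axis, log scale); points are libraries and bars the means of 2. For the A chain, the pair A libraries lie at 66497 and 144998, the pair B libraries at 647 and 796, and the DkdpE libraries at 720 and 873.

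Other transporters of potassium and sodium moved less. Reads of the Kup potassium uptake protein (CCNA_00130) were 1.61-fold lower in pair A (−0.68 ± 0.14), and those of a potassium channel (CCNA_01688) 1.27-fold higher (0.34 ± 0.11). The potassium efflux genes kefB (−0.03 ± 0.11) and kefC (−0.04 ± 0.12) did not pass the test. Both sodium/proton antiporters were higher: CCNA_01568 by 2.02-fold (1.02 ± 0.13) and nhaA by 1.63-fold (0.71 ± 0.18). Of 3 mechanosensitive channels, which open under membrane tension, CCNA_03095 was 1.99-fold higher (0.99 ± 0.15), CCNA_03700 was 1.52-fold lower (−0.60 ± 0.18), and mcsS did not pass (−0.31 ± 0.11). The calls of CCNA_00130 (−0.68 and −0.69) and CCNA_01688 (0.40 and 0.29) were lost without replicate 1 or 2 of pair B, that of CCNA_03700 without replicate 1 (−0.53), and that of nhaA without replicate 2 (0.63). The call of CCNA_01688 was also lost with quantile normalisation (0.26) and, at an unchanged fold change, without the trend on the spread. By contrast, mcsS passed with quantile normalisation (−0.40), in a fit of all 6 libraries (−0.31) and without replicate 1 (−0.35) or replicate 2 (−0.26) of pair A. The values of kefB and kefC, near 0, changed sign with equal library totals (0.02 and 0.01) and without replicate 2 of pair A (0.00372 and 0.06).

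Genes of protein synthesis were lower in pair A. All 55 ribosomal protein genes fell, also adjusted over the list alone, with a median log2 fold change of −1.22 (camera adjusted p = 1.08e-17; adjusted p = 0.690 with an estimated correlation). Among them, rpsS was 3.44-fold lower (−1.78 ± 0.17), rplB 3.38-fold lower (−1.76 ± 0.18) and rplW 3.27-fold lower (−1.71 ± 0.17). Of 22 aminoacyl-tRNA synthetase genes, which charge transfer RNAs, 19 fell and none rose, and 21 fell adjusted over the list alone (median −0.80, camera adjusted p = 2.53e-06; adjusted p = 0.690 with an estimated correlation). The phenylalanyl-tRNA synthetase beta subunit (CCNA_01095) was 2.08-fold lower (−1.05 ± 0.15) and the aspartyl-tRNA synthetase (CCNA_01969) 2.07-fold lower (−1.05 ± 0.15). Amino acid biosynthesis genes went the same way, with 15 of 18 lower, also adjusted over the list alone (median −0.70, camera adjusted p = 7.20e-05; adjusted p = 0.690 with an estimated correlation). That list held leuB, an enzyme of leucine synthesis, at 1.82-fold lower (−0.87 ± 0.19), and the sulfate transporter genes cysW (−0.84 ± 0.20) and cysT (−0.82 ± 0.15).

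Genes of the FixLJ pathway, which answers low oxygen, were higher in pair A. Of 16 members, 15 rose and none fell, and 16 rose adjusted over the list alone (median 1.34, camera adjusted p = 7.20e-05; adjusted p = 0.690 with an estimated correlation). The cytochrome bd oxidase genes cydA and cydB were 7.23-fold (2.85 ± 0.41) and 5.26-fold higher (2.39 ± 0.34), and the regulator ftrB 6.31-fold higher (2.66 ± 0.55). The replicates of pair A lay apart in these genes: cydA had 60389 and 154889 normalised counts in pair A, against 14997 and 11923 in pair B. Without replicate 1 of pair A cydA stood at 3.53 and ftrB at 3.61, and without replicate 2 at 2.17 and 1.70. The wider list of ATP synthase and respiration moved both ways, with 29 of 45 members lower and 9 higher, or 30 and 9 adjusted over the list alone (median −0.54, camera adjusted p = 0.00305; adjusted p = 0.690 with an estimated correlation). Its members with the largest changes were cydA, cydB and ccoN, the last a subunit of the cbb3 oxidase at 3.71-fold higher (1.89 ± 0.39), against the direction of the list. Without replicate 1 and replicate 2 of pair A, ccoN stood at 2.54 and 1.25. Its list call was lost without replicate 1 (median −0.52) or replicate 2 (−0.51) of pair B.

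Iron genes were lower in pair A in 11 of 15 members and higher in 2, also adjusted over the list alone (median −0.77, camera adjusted p = 0.00305; adjusted p = 0.690 with an estimated correlation). The hemin receptor gene hutA was 4.74-fold lower (−2.24 ± 0.23) and the ferrous iron transporter gene CCNA_00749 2.57-fold lower (−1.36 ± 0.27), while hemN, a heme synthesis gene that also stood in the FixLJ list, was 4.80-fold higher (2.26 ± 0.47, with 3.06 and 1.47 without replicate 1 and replicate 2 of pair A). Of 12 genes of the S-layer and surface polysaccharides, 9 fell and 1 rose, or 10 and 1 adjusted over the list alone (median −0.61, camera adjusted p = 0.00735; adjusted p = 0.690 with an estimated correlation). They included rsaE, which exports the S-layer protein (−0.93 ± 0.16), lpxD, a lipid A synthesis gene (−0.88 ± 0.13), and rfbB (−0.81 ± 0.16). The envelope stress list had 9 of 20 members lower and none higher, also adjusted over the list alone (median −0.22, camera adjusted p = 0.0240; adjusted p = 0.690 with an estimated correlation). Its largest changes were in the outer membrane receptor gene chvT, at 2.11-fold lower (−1.08 ± 0.20), and the efflux pump genes acrB (−1.08 ± 0.18) and acrB2 (−1.07 ± 0.11). That list call was lost without replicate 1 (median −0.18) or replicate 2 (−0.29) of pair B and with quantile normalisation (−0.26).

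Of 94 flagellum and chemotaxis genes, 26 rose and 8 fell in pair A, or 21 and 6 adjusted over the list alone (median 0.19, camera adjusted p = 0.0364; adjusted p = 0.690 with an estimated correlation). The largest changes were in flmH, 10.5-fold higher (3.40 ± 0.70), and in the chemoreceptor genes CCNA_00437, 3.83-fold higher (1.94 ± 0.16), and CCNA_00064, 2.81-fold higher (1.49 ± 0.22). The replicates of pair A lay apart in flmH, with 1554 and 8426 normalised counts; without replicate 1 it stood at 4.62 and without replicate 2 at 2.18. The list call was lost without replicate 1 of pair A (median 0.12) and without replicate 1 (0.14) or replicate 2 (0.21) of pair B, and the median was 0.13 with quantile normalisation. TonB-dependent transport genes, outer membrane receptors for scarce nutrients, split into 23 higher and 16 lower of 65, also adjusted over the list alone (median 0.10, camera adjusted p = 0.249). The receptor genes CCNA_01859 (10.1-fold, 3.34 ± 0.20), CCNA_03096 (6.29-fold, 2.65 ± 0.18) and CCNA_03298 (5.07-fold, 2.34 ± 0.15) were higher. Of 37 heat shock and proteolysis genes, 7 rose and 16 fell, also adjusted over the list alone (median −0.17, camera adjusted p = 0.102). The chaperonin genes for GroES (CCNA_00722) and GroEL (CCNA_00721) were 4.31-fold (−2.11 ± 0.20) and 3.75-fold lower (−1.91 ± 0.19), and a dnaK gene (CCNA_01543) 2.45-fold lower (−1.29 ± 0.16). The list call of heat shock genes passed without replicate 2 of pair A alone (median −0.16, adjusted p = 0.0495; adjusted p = 0.869 with an estimated correlation).

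The other lists did not pass camera between the wild-type pairs. In the general stress response list, 7 of 16 members rose and 5 fell, or 8 and 5 adjusted over the list alone (median 0.24, adjusted p = 0.496). A superoxide dismutase gene (CCNA_01855) was 7.34-fold higher (2.88 ± 0.21), the catalase gene katG 6.05-fold higher (2.60 ± 0.22) and the sigma factor gene sigU 3.05-fold higher (1.61 ± 0.24). In central carbon metabolism 3 of 9 rose and 5 fell, or 4 and 5 adjusted over the list alone (median −0.57, adjusted p = 0.606), with sucD lower by 1.95-fold (−0.96 ± 0.18). Phosphate uptake had 1 of 12 higher and 5 lower, also adjusted over the list alone (median −0.31, adjusted p = 0.249), with ppk2 at 0.94 ± 0.13 and pstC at −0.81 ± 0.15. Nitrogen and glutamate genes had 5 of 25 higher and 4 lower, or 4 and 4 adjusted over the list alone (median 0.02, adjusted p = 0.843), with glnC at 0.81 ± 0.14 and glnE at 0.75 ± 0.12. Of 40 cell cycle genes, 3 rose and 8 fell, also adjusted over the list alone (adjusted p = 0.598); their median was 0.02 while their mean, −0.07, and the test pointed down. The division regulator gene mipZ was higher (1.06 ± 0.21) and the chromosome partitioning gene parB lower (−0.98 ± 0.16). Swarmer cell markers had 3 of 20 higher and 1 lower, or 1 and 0 adjusted over the list alone (median 0.01, adjusted p = 0.743), with cheY 2.64-fold higher (1.40 ± 0.16). Stalked cell markers had 1 of 12 higher and 1 lower (median 0.08, adjusted p = 0.888), pilus and holdfast genes 2 of 31 higher and 2 lower (median −0.05, adjusted p = 0.743), and the SOS response 3 of 12 higher and 1 lower (median 0.03, adjusted p = 0.843). Adjusted over the list alone, 0 members of each of these 3 lists passed in limma; at an unadjusted p under 0.05 there were 3, 5 and 4. Medians near 0 changed sign with 1 library left out: nitrogen and glutamate without replicate 1 of pair B (−0.03), swarmer cell markers without replicate 1 of pair A (−0.05) or of pair B (−0.00323), and pilus and holdfast (0.00861) and the SOS response (−0.05) without replicate 2 of pair A. With quantile normalisation the median of the SOS response was −0.02 and that of central carbon metabolism −0.36.

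Outside the lists, CCNA_03313, a hypothetical protein gene, was 39.9-fold higher in pair A (5.32 ± 0.40), the PhoH protein gene CCNA_02727 19.7-fold (4.30 ± 0.29) and a host cell attachment protein gene, CCNA_02604, 16.2-fold (4.02 ± 0.59). CCNA_03906 (15.6-fold, 3.96 ± 0.53), CCNA_03970 (12.5-fold, 3.65 ± 0.33) and the 3-ketoacyl-CoA thiolase gene CCNA_02490 (11.2-fold, 3.49 ± 0.39) completed the 10 largest increases. The replicates of pair A lay apart in several: without replicate 1 and without replicate 2, CCNA_03313 stood at 5.98 and 4.66, CCNA_02604 at 5.04 and 2.996, CCNA_03906 at 4.87 and 3.06, and CCNA_02490 at 4.14 and 2.84. Among called genes with a mean of at least 50 and no overlap between the pairs, the largest decreases were in the transporter gene CCNA_03022, 4.79-fold lower (−2.26 ± 0.26), hutA, and the EF-hand protein gene CCNA_02274, 4.58-fold lower (−2.20 ± 0.24). They went on with CCNA_03158 (−2.12 ± 0.28), CCNA_03159 (−2.11 ± 0.24) and CCNA_03157 (−1.95 ± 0.29), of which the first is an iron-sulfur cluster assembly or repair gene, with the phytase gene CCNA_01353 (−2.07 ± 0.29), and with CCNA_02275 (−2.05 ± 0.26) and the small RNA CCNA_R0211 (−1.99 ± 0.28).

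Of 4002 genes tested with limma, 2175 differed between the pairs, 1093 higher and 1082 lower in pair A, and 633 of them differed by a log2 of at least 1, 399 higher and 234 lower. The balance depended on the scaling, with 1179 higher and 972 lower at equal library totals, and 945 and 1193 with quantile normalisation. The authors' deposited table called 2159 genes for the same libraries, 2103 of them among the 2175. Without replicate 1 of pair B 1389 genes were called, and without replicate 2 1339. Fold changes are on the log2(normalised count + 1) scale, which understates the changes of genes with low counts.

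DkdpE was compared with pair A, wild type at the same potassium by the deletion tables, to ask which genes depend on KdpE. The Kdp genes were the 5 largest decreases among the named genes. Besides kdpE itself (201-fold lower, −7.65 ± 0.26), the B chain (CCNA_01664) was 146-fold lower in DkdpE (−7.19 ± 0.24, adjusted p = 9.76e-07), the A chain (CCNA_01663) 123-fold (−6.94 ± 0.31), the C chain (CCNA_01665) 36.1-fold (−5.17 ± 0.19) and kdpD also lower (−4.36 ± 0.16). All 5 fell over all genes, adjusted over the list alone, and under every alternative that was run (camera adjusted p = 1.15e-22; adjusted p = 0.659 with an estimated correlation). The Kdp list held kdpE, whose fall the deletion itself set, and was not tested without it. In a fit of all 6 libraries, DkdpE and pair B did not pass the test in the B chain (0.13 ± 0.23), the A chain (0.14 ± 0.32) or kdpD (0.35 ± 0.13), while the C chain was higher in DkdpE (0.67 ± 0.17, adjusted p = 0.0111). Potassium transport outside Kdp did not pass in DkdpE: CCNA_00130 stood at 0.01 ± 0.17, CCNA_01688 at −0.09 ± 0.14, kefB at 0.07 ± 0.14 and kefC at −0.41 ± 0.15. Nor did the antiporter genes CCNA_01568 (0.10 ± 0.16) and nhaA (0.72 ± 0.19), or the channel genes CCNA_03095 (0.16 ± 0.16), mcsS (−0.13 ± 0.14) and CCNA_03700 (−0.13 ± 0.19). Without replicate 2 of pair A, however, nhaA (0.97) and kefC (−0.52) passed and CCNA_00130 stood at −0.14. Without replicate 1 of pair A, CCNA_01568 (−0.00903), CCNA_03095 (−0.02) and CCNA_03700 (0.13) changed sign.

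Outside Kdp, the largest decrease among called genes in DkdpE was in the ABC transporter permease gene CCNA_01588, 7.75-fold lower (−2.95 ± 0.48, with −3.77 and −2.14 without replicate 1 and replicate 2 of pair A). Next, the TonB-dependent receptor genes CCNA_01859 and CCNA_01585 were 5.79-fold (−2.53 ± 0.30) and 5.26-fold lower (−2.40 ± 0.37). The authors' deposited table gave smaller log2 fold changes, as pair A over DkdpE. They were 0.59 for CCNA_01588, which that table did not call (its adjusted p = 0.0578), 1.74 for CCNA_01859 and 0.73 for CCNA_01585. For the Kdp genes too that table gave smaller values, 5.44 for the B chain, 4.59 for the A chain, 4.34 for the C chain, 3.87 for kdpD and 5.90 for kdpE. The hemin receptor gene hutA was 5.12-fold lower (−2.36 ± 0.25), the EF-hand protein gene CCNA_02274 4.55-fold lower (−2.19 ± 0.26) and the AraC family regulator gene CCNA_01858 3.82-fold lower (−1.93 ± 0.28). In the iron list hutA and the bacterioferritin-associated ferredoxin gene CCNA_03372 (−1.21 ± 0.17) fell, 2 of 15, also adjusted over the list alone (median −0.01, camera adjusted p = 0.274). Of 65 TonB-dependent transport genes 2 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.874); their mean was −0.02 while the median, 0.01, and the test pointed up. In the general stress list the superoxide dismutase gene CCNA_01855 fell (−1.42 ± 0.27), 1 of 16, or 1 lower and 1 higher adjusted over the list alone (median 0.10, adjusted p = 0.874). With robust limma the calls of CCNA_01588, CCNA_01585, CCNA_01858, CCNA_01859 and CCNA_01855 were lost at the same fold changes (adjusted p between 0.0774 and 0.348). Those of CCNA_01588, CCNA_01585 and CCNA_01855 were lost without the trend too, and those of CCNA_01588 (−2.96) and CCNA_01855 (−1.40) with quantile normalisation. Without replicate 2 of DkdpE the median of TonB-dependent transport was −0.04, and without replicate 1 that of the general stress list −0.00603.

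The largest increases in DkdpE were in osrP, 3.31-fold (1.73 ± 0.26), CCNA_00224, a hypothetical protein gene, 3.13-fold (1.65 ± 0.17), and the acetolactate synthase small subunit gene CCNA_02186, 3.03-fold (1.60 ± 0.22). They went on with the genes for hypothetical proteins CCNA_00913 (1.43 ± 0.15), CCNA_00768 (1.42 ± 0.17), CCNA_02723 (1.41 ± 0.18), CCNA_03098 (1.41 ± 0.16) and CCNA_02758 (1.38 ± 0.19), and with the TonB-dependent receptor gene CCNA_00858 (1.39 ± 0.21). The chaperonin genes for GroEL (CCNA_00721) and GroES (CCNA_00722) were 2.76-fold (1.46 ± 0.21) and 2.60-fold higher (1.38 ± 0.20), and the small heat shock protein gene CCNA_02341 1.83-fold higher (0.87 ± 0.16). As a list, heat shock and proteolysis stood above the other genes, with 3 of 37 members higher and none lower, or 4 and 0 adjusted over the list alone (median 0.15, camera adjusted p = 0.000868; adjusted p = 0.845 with an estimated correlation). The stalked cell marker spmX, which localises a histidine kinase to the stalked pole, was 2.53-fold higher (1.34 ± 0.17), and bacB, a cytoskeletal gene, 1.83-fold higher (0.87 ± 0.16). That made 2 of 12 stalked cell markers, or 3 adjusted over the list alone (median 0.08, camera adjusted p = 0.140). Without replicate 2 of DkdpE the calls of CCNA_00858 (1.16), CCNA_00721 (1.26), CCNA_00722 (1.19), CCNA_02341 (0.77) and bacB (0.93) were lost, as was the list call of heat shock genes (median 0.14, adjusted p = 0.0506). Without replicate 1 those of CCNA_02341 (0.98) and bacB (0.81) were lost. Both were lost without the trend too, and that of bacB with quantile normalisation (0.86).

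Other lists passed camera with few or no members passing in limma. The 94 flagellum and chemotaxis genes stood above the other genes in DkdpE (median 0.21, camera adjusted p = 1.94e-06; adjusted p = 0.845 with an estimated correlation). By limma 0 of them passed, also adjusted over the list alone, with 16 at an unadjusted p under 0.05, against 569 of all 4007 genes. The chemoreceptor gene CCNA_00538 stood at 0.71 ± 0.17, and passed in the fit of all 6 libraries (0.70) and without replicate 1 (0.78) or replicate 2 (0.64) of pair A. ATP synthase and respiration stood above the other genes (median 0.31, camera adjusted p = 0.00298; adjusted p = 0.928 with an estimated correlation), with 1 of 45 members passing, also adjusted over the list alone, the ATP synthase epsilon subunit gene CCNA_03558 (0.85 ± 0.16). Aminoacyl-tRNA synthetases stood below the other genes (median −0.15, camera adjusted p = 0.0393; adjusted p = 0.945 with an estimated correlation), with 0 of 22 passing in limma, also adjusted over the list alone, and 3 at an unadjusted p under 0.05. Tested against no change by fry, in 1 direction, none of these 3 lists passed (adjusted p = 0.272, 0.539 and 0.791). The synthetase call was lost without replicate 1 (median −0.11) or replicate 2 (−0.22) of DkdpE and without replicate 1 of pair A (−0.03), and the respiration call without replicate 2 of DkdpE (median 0.26). Without replicate 2 of pair A these medians were −0.27 and 0.19. Without replicate 2 of DkdpE 2 lists passed and without replicate 1 of pair A 8, against 5 with all libraries. The call of CCNA_03558 was lost without replicate 1 (0.74) or replicate 2 (0.96) of DkdpE, with quantile normalisation (0.83) and without the trend.

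The remaining lists did not pass camera in DkdpE with all libraries. Ribosomal protein genes had 1 of 55 higher, rpmC (0.79 ± 0.15), or 8 higher and 3 lower adjusted over the list alone (median 0.10, adjusted p = 0.274). Their median depended on the replicate of pair A: the list passed without replicate 1 (0.30, adjusted p = 4.06e-07; adjusted p = 0.803 with an estimated correlation) and stood at −0.17 without replicate 2, and at 0.00166 without replicate 2 of DkdpE. Envelope stress genes had 2 of 20 higher, the efflux genes acrB (0.99 ± 0.19) and CCNA_00849 (0.76 ± 0.13), or 3 adjusted over the list alone (adjusted p = 0.874); their median was −0.10 while the mean, 0.06, and the test pointed up. In nitrogen metabolism the glutamate synthase gene gltD rose (1.14 ± 0.20), 1 of 25, or 1 higher and 2 lower adjusted over the list alone (median −0.05, adjusted p = 0.184). In amino acid biosynthesis the sulfate assimilation gene cysH rose (0.99 ± 0.21), 1 of 18, also adjusted over the list alone (adjusted p = 0.874), with a mean of 0.02 while the median, −0.09, and the test pointed down. Without replicate 1 of pair A the amino acid list passed in the other direction (median 0.10, adjusted p = 0.0181; adjusted p = 0.803 with an estimated correlation). The calls of rpmC (0.77 and 0.81), acrB (1.07 and 0.91), CCNA_00849 (0.73 and 0.78), gltD (1.31 and 0.97) and cysH (0.96 and 1.03) were lost without replicate 1 or replicate 2 of DkdpE. All 5 were lost without the trend too, those of rpmC (0.78), acrB (0.98) and cysH (0.97) with quantile normalisation, and that of cysH without the filter on low values (0.99), with trimmed-mean scaling (0.99) and after thinning of DkdpE replicate 1 (0.99).

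By limma 0 members passed, also adjusted over the list alone, in 8 more lists. Their medians were 0.33 in the FixLJ list (16 genes, camera adjusted p = 0.0898), with hemN at 1.11 ± 0.42, and 0.20 in swarmer cell markers (20 genes, adjusted p = 0.101), with cheY at 0.51 ± 0.19. Central carbon metabolism had a median of 0.17 (9 genes, adjusted p = 0.196), with sucB at 0.49 ± 0.19, and pilus and holdfast 0.11 (31 genes, adjusted p = 0.151), with hfsL at 0.38 ± 0.13. Cell cycle genes had a median of −0.01 (40 genes, adjusted p = 0.874), with rcdA at 0.44 ± 0.15, and phosphate uptake −0.02 (12 genes, adjusted p = 0.874), with phnC at −0.42 ± 0.14. The SOS response had a median of −0.06 (12 genes, adjusted p = 0.885), with ruvC at 0.38 ± 0.14. S-layer and surface polysaccharide genes had a median of 0.00333 (12 genes, adjusted p = 0.874), while their mean, −0.01, and the test pointed down, with rfbB at −0.54 ± 0.17. At an unadjusted p under 0.05 these 8 lists together had 13 distinct members. The FixLJ median depended on the replicate of pair A, at −0.07 without replicate 1 and 0.80 without replicate 2, where the list passed (adjusted p = 2.84e-10; adjusted p = 0.818 with an estimated correlation). That list also passed with equal library totals (0.29; adjusted p = 0.934 with an estimated correlation) and without replicate 1 of DkdpE (0.40; adjusted p = 0.979 with an estimated correlation). Swarmer cell markers (0.30) and pilus and holdfast (0.18) passed without replicate 1 of pair A (each with an adjusted p = 0.803 with an estimated correlation). So did sucB (0.63), while hemN (1.90), cheY (0.69), rcdA (0.51), phnC (−0.50) and rfbB (−0.76) passed without replicate 2 of pair A; hemN stood at 0.33 without replicate 1. Medians near 0 changed sign for phosphate uptake without replicate 1 of DkdpE (0.00478) or of pair A (0.00957), and for the SOS response without replicate 2 of pair A (0.01), while that of the S-layer list was 0.13 without replicate 1 of pair A.

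**Figure D2:**
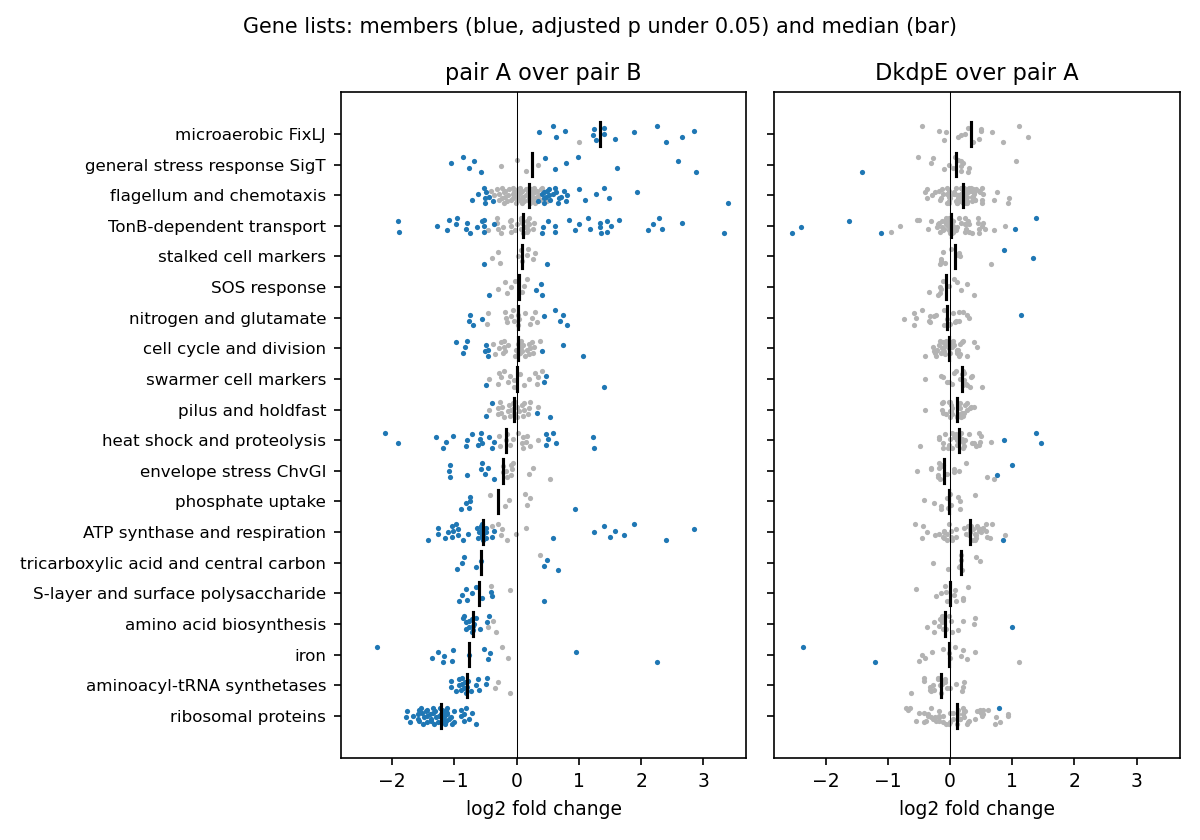
Log2 fold changes of the members of 20 gene lists (points, blue where the adjusted p was under 0.05) with each list's median (bar), pair A over pair B at left and DkdpE over pair A at right; the Kdp list is left out. The 55 ribosomal protein genes lie below 0 at left, with a median of −1.22, and around 0 at right, with a median of 0.10.

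Of 4007 genes tested with limma, 86 differed between DkdpE and pair A, 49 higher and 37 lower in DkdpE, and 57 of them differed by a log2 of at least 1, 26 higher and 31 lower. With robust limma 62 were higher and 32 lower, while more were lower than higher without replicate 1 or without replicate 2 of DkdpE. The authors' deposited table called 184 genes for these libraries, 85 of them among the 86, the exception being CCNA_01588. Without replicate 1 of DkdpE 55 genes were called, without replicate 1 of pair A 309 and without replicate 2 of pair A 557, with all 86 kept in the last pair of fits. With quantile normalisation 57 genes were called and without the trend on the spread 45.

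Genes called in both comparisons were counted to ask how much of the difference between the wild-type pairs went back in DkdpE. Of 4001 genes tested in both, 22 were higher in pair A than in pair B and lower in DkdpE than in pair A, and 11 were lower and then higher. The first set held the Kdp genes, the deleted kdpE among them. It also held the TonB-dependent receptor gene CCNA_01859, the regulator gene CCNA_01858 beside it (3.37 ± 0.27 and then −1.93 ± 0.28) and the permease gene CCNA_01588 (2.78 ± 0.48 and then −2.95 ± 0.48; for the first, 3.60 and 1.95 without replicate 1 and replicate 2 of pair A). The second held GroEL (CCNA_00721) and GroES (CCNA_00722). A further 32 genes differed the same way in both steps, 17 higher and higher again and 15 lower and lower again. They included osrP (2.65 ± 0.24 and then 1.73 ± 0.26) and the nucleoside permease gene CCNA_01700 (2.55 ± 0.23 and then 1.37 ± 0.23) upward, of which the second call of CCNA_01700 was lost without the trend. Downward they included hutA (−2.24 ± 0.23 and then −2.36 ± 0.25), its neighbours CCNA_02274 (−2.20 ± 0.24 and then −2.19 ± 0.26) and CCNA_02275 (−2.05 ± 0.26 and then −2.05 ± 0.25), the phytase gene CCNA_01353 (−2.07 ± 0.29 and then −1.95 ± 0.27), the TonB-dependent receptor gene CCNA_00028 (−1.91 ± 0.28 and then −1.62 ± 0.26) and CCNA_03904 (−1.50 ± 0.24 and then −1.93 ± 0.23).

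Independent lists of these sizes would share 10.1 genes in the first set, 13.2 in the second, 13.4 higher and higher and 10 lower and lower, and simulated unchanged groups that share the pair A libraries gave 0 genes in either direction. No simulation called a gene between the pairs, so that 0 was fixed beforehand and says nothing of chance for the 33 and 32 genes. Across genes, which are not independent replicates, the fold changes of the comparisons had a correlation of 0.00331 (−0.69 in the simulation) and a covariance of 0.00107 (−0.0315 in the simulation). The 5 Kdp genes, large and opposite, weighed on these values: without them the correlation was 0.17 and the covariance 0.0438. Part of any excess in opposite directions may come from the shared libraries, since a split leaves 1 library of pair A on each side. In simulated unchanged groups sharing did not add to the same direction. A pair A library that lies toward pair B can add to it, and such a library was not simulated. With replicate 1 against pair B and replicate 2 against DkdpE, the correlation was −0.26, and with the replicates exchanged 0.33. Without replicate 1 of pair A the counts were 189 opposite and 74 the same way, and without replicate 2 they were 78 and 401, against 33 and 32 with all libraries.

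**Figure D3:**
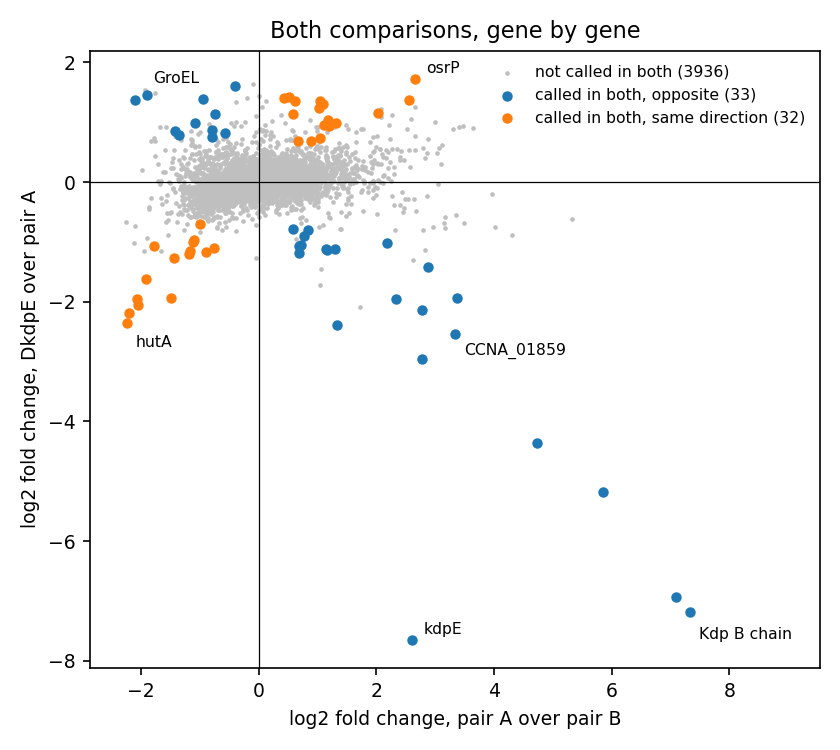
Log2 fold change of pair A over pair B (horizontal) against that of DkdpE over pair A (vertical) for the 4001 genes tested in both; blue points are the 33 genes called in both with opposite signs and orange points the 32 with the same sign. The B chain of the Kdp ATPase lies at 7.33 and −7.19, and hutA at −2.24 and −2.36.

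DkdpE was also set against pair B, with all 6 libraries in one fit of the recovered reads. Of 4007 genes 2481 differed, 1255 higher and 1226 lower in DkdpE, and 2030 of the 2274 genes that differed between the wild-type pairs in this fit differed the same way, with 5 the other way. Independent lists of 2274 and 2481 genes would share 704 in the same direction. Of the Kdp genes, the A chain (CCNA_01663), the B chain (CCNA_01664) and kdpD, all called between the wild-type pairs, did not pass between DkdpE and pair B, while the C chain (CCNA_01665) was higher in DkdpE (0.67 ± 0.17), as in pair A. The deleted kdpE was lower (−5.06 ± 0.25). Of 627 genes that differed between the pairs by a log2 of at least 1 in this fit, 598 differed the same way in DkdpE. The correlation of the fold changes across genes was 0.90 (0.24 in simulated unchanged groups that share pair B) and the covariance 0.650 (0.00832 in the simulation). In that simulation the shared libraries of pair B gave only a small part of the covariance found. A deviation common to both libraries of pair B would add to it and was not tested, since they cannot be split with 2 on each side.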

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

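Of the alternatives below, the thinning of DkdpE replicate 1 and the use of the joint fit for genes called in both comparisons were chosen after seeing the data. The 5 Kdp genes kept their calls and directions in both comparisons under every alternative run, and no value past the threshold changed direction. A list that was not called, amino acid biosynthesis in DkdpE over pair A (median −0.09), passed in the other direction without replicate 1 of pair A (0.10; adjusted p = 0.803 with an estimated correlation). Between the wild-type pairs, 2175 genes were called; this became 1274 at an adjusted p of 0.01 and 633 with a log2 of at least 1, and ranged from 1339 to 2796 with 1 library left out. Between DkdpE and pair A, 86 became 57 with quantile normalisation, 45 without the trend, 29 at an adjusted p of 0.01 and 57 with a log2 of at least 1, and ranged from 55 to 557 with 1 library left out; thinning DkdpE replicate 1 to the depth of replicate 2 gave 76 and the joint fit 128. The 10 lists called between the wild-type pairs became 0 with an estimated correlation, 1 with fry and 20 with fry in either direction. The 5 lists called for DkdpE became 0, 1 and 12, and 2 to 8 with 1 library left out. The causes were not tested, apart from the stricter thresholds and the fewer samples that some alternatives consist of.

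Genes called in both comparisons numbered 33 opposite and 32 the same way. They were 18 and 17 with a log2 of at least 1 in both, and ranged from 22 to 189 and from 23 to 401 with 1 library left out. With pair A split, they were 167 and 81 with replicate 1 against pair B and replicate 2 against DkdpE, and 72 and 433 the other way round; in the joint fit they were 48 and 45. For DkdpE against pair B, 2481 became 1775 to 1999 with 1 library left out. The replicate numbers share no stated origin, and the deviations of same-numbered libraries correlated at −0.07 for pairs A and B, 0.20 for pair A and DkdpE and 0.21 for pair B and DkdpE. A replicate block gave 2119 genes between the wild-type pairs, 245 between DkdpE and pair A, 2524 between DkdpE and pair B, and 76 opposite and 125 the same way in both. Among the genes and lists of the text, it ended the calls of CCNA_01688 and of the flagellum and chemotaxis list between the wild-type pairs and of the synthetase list for DkdpE. For DkdpE, nhaA, hemN, cheY, CCNA_00538, rfbB and the FixLJ list (camera adjusted p = 0.972 with an estimated correlation) passed under it. Tests on counts with edgeR and DESeq2 were not run, since the low values per column were too few to establish the read counts independently. Simulated changes of a log2 of 0.5, with a spread independent between genes, were called in 35.8% and 37.3% of genes in the comparisons. Most changes of that size were thus missed in the simulation, and smaller ones were not simulated. The simulation held 200 changed genes, while 2175 genes were called between the wild-type pairs, so its shares may not hold there. Between those pairs some smaller changes were called: CCNA_01688 (0.34) passed with all libraries, while mcsS (−0.31) did not.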

Other observations

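The gene groups and the neighbour count below, and all tests of explanations except that of the mixing fraction, were chosen after the results were seen; the Kdp counts of each replicate had been seen before that one too. Groups of genes by type or product word were also tested, 175 in all. Of 51 transfer RNA genes, 40 fell in pair A over pair B and none rose, with a median of −0.995 (camera adjusted p = 7.67e-10 over all groups; adjusted p = 0.724 with an estimated correlation). The isoleucine transfer RNA CCNA_R0068 was 3.16-fold lower (−1.66 ± 0.17). Genes with the word elongation in their product went with them, with 8 of 8 lower (median −0.95, adjusted p = 0.00629; adjusted p = 0.724 with an estimated correlation), among them the elongation factor Tu gene CCNA_03303 at 2.55-fold lower (−1.35 ± 0.15). Of 11 phage products, 10 rose and 1 fell (median 1.74, adjusted p = 0.00104; adjusted p = 0.724 with an estimated correlation); the prohead protease gene CCNA_02872 was 5.45-fold higher (2.45 ± 0.15) and the packaging protein gene CCNA_02880 4.34-fold higher (2.12 ± 0.17). Of 38 genes for acyl-CoA enzymes, many of which serve fatty acid breakdown, 25 rose and 4 fell (median 0.63, adjusted p = 0.000508; adjusted p = 0.724 with an estimated correlation), in a group formed from any product name that holds acyl-CoA. The 29 of them with acyl-CoA as a separate word had 18 higher and 4 lower (median 0.62, adjusted p = 0.00815; adjusted p = 0.724 with an estimated correlation). Among them was the synthetase gene CCNA_01017 at 4.31-fold higher (2.11 ± 0.21). The medians of the transfer RNA, elongation, phage and 38-gene acyl-CoA groups kept their sign under each of the scalings tried. The group of 29 was not run under them. In DkdpE over pair A the transfer RNA genes had a median of −0.30 (adjusted p = 0.000233; adjusted p = 0.973 with an estimated correlation), and 0 of 51 passed in limma. Products with methyl-accepting (19 genes, median 0.29, camera adjusted p = 0.000751) and NADH-quinone (14 genes, 0.40, 0.00116) stood above the other genes. With an estimated correlation each had an adjusted p = 0.973, and 0 members passed in limma. Between the wild-type pairs their medians were 0.49 and −0.54.

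Genes that differed between DkdpE and pair A lay side by side: 36 of the 86 had a called neighbour of the same direction, against a mean of 1.83 and a highest value of 14 in 10000 random placements (permutation p = 1e-04, the smallest they can give). There were 13 such runs, the Kdp operon among them. The placements moved each gene on its own, so neighbours transcribed together can give such runs in any list of changed genes. The calls between the wild-type pairs were not tested in this way, so the p says nothing particular to DkdpE. Besides the 5 Kdp genes, 4 neighbouring riboflavin synthesis genes were lower in DkdpE, CCNA_00929 (−1.08 ± 0.17), CCNA_00930 (−1.19 ± 0.16), CCNA_00931 (−1.05 ± 0.16) and ribH (−0.90 ± 0.16). The efflux genes CCNA_02172 (1.26 ± 0.17), CCNA_02173 (1.01 ± 0.16) and CCNA_02174 (0.89 ± 0.17) were higher. Without replicate 2 of DkdpE the calls of all 7 were lost (−0.90, −1.07, −1.01, −0.94, 1.17, 1.02 and 1.003), and without replicate 1 those of CCNA_00931 (−1.099), ribH (−0.87), CCNA_02173 (0.99) and CCNA_02174 (0.78).

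The headings give pair A high potassium in 1 table and low potassium in the other 3. A candidate explanation is that the wild-type headings of that 1 table are exchanged: DkdpE, labelled low potassium, then shares its potassium level with pair A, and 128 genes differed between them in the joint fit, against 2481 between DkdpE and pair B. If that 1 heading were right and the other 3 tables wrong, the deletion alone would set DkdpE apart from pair B, with no bound on the number of genes, so the 2481 genes do not decide against it and the explanations cannot be told apart by that count. That reading would also need the A, B and C chain genes of the high-affinity pump, 58.0-fold to 161-fold higher in pair A, to be higher at 5 mM than at 0.025 mM K+, the reverse of what is known of such pumps, but how they respond in these cells was itself the question. No library outside these 6 was there to settle the potassium level.

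Replicate 1 of pair A lay between replicate 2 and pair B in 594 of the 633 genes that differed between the pairs by a log2 of at least 1, or 93.8%. Cells or RNA of the pair B kind in replicate 1 would give 1 mixing fraction for all genes, but over the 154 genes that differed 4-fold or more between replicate 2 and pair B the fraction had an interquartile range of 0.260. Its median was 0.50 in the 136 genes higher in replicate 2 and 0.15 in the 18 lower ones, which argues against mixing as the whole cause. A depth ratio of 1.02 between the replicates argues against depth. A different state of the cultures at harvest stays open and was not tested.

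The 32 genes that differed in DkdpE from pair A in the direction in which pair A differed from pair B, such as hutA, were weighed last. Independent lists of these sizes would already share 13.4 genes higher and higher and 10 lower and lower, against 17 and 15 found. Pair A enters the comparisons with opposite signs, so in unchanged groups shared libraries give a negative covariance by construction (−0.0315 in the simulation). In such groups sharing thus does not add to the same direction, but that sign was fixed beforehand and says nothing of chance otherwise. It does not cover a pair A library that lies toward pair B. With the deep DkdpE replicate 1 left out, 23 genes were still called the same way in both comparisons, 20 of them among the 32, which argues against its depth as the whole cause; thinning replicate 1 kept 25 of the 32 calls, and in the other 7 the log2 fold change moved by at most 0.03, the standard errors stayed between 0.14 and 0.25, and the adjusted p went from between 0.0378 and 0.0499 to between 0.0518 and 0.0595. A pull of replicate 1 of pair A toward pair B stays open: all 32 stayed called with replicate 2 alone, but so did all 86 genes, so that count decides nothing, and their median size was 0.89 against replicate 2 and 1.496 against replicate 1. That DkdpE cells were shorter of potassium than wild type may be a biological cause, and it was not tested.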
